A study of Mus musculus with 86 samples.

How the data were processed

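The labels give 86 mouse samples, 32 of the knockout experiment (kidney and liver) and 54 of the inhibitor experiment (kidney, liver and lung). Per the labels, samples differ in tissue, genotype and treatment, and no label says which samples share an animal, a batch or a day. RNA was extracted with a Qiagen mini kit, and libraries were made with the unstranded TruSeq RNA v2 kit and read at 100 bases on a HiSeq 2000, per the labels' protocols. FastQC, Trim Galore, STAR and edgeR were used without stated versions, and the builds hg38 and mm10 are named, per the submitters' processing notes.

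The deposited files of the knockout experiment hold raw counts per gene in the layout of STAR, and the column that ignores strand was used. Reads in genes ranged from 7.22 to 28.5 M in kidney (median 16.3 M) and from 14.5 to 23.4 M in liver. The kidney library sham WT 3 had 58.5% unmapped reads and UUO KO 4 had 32.02%. The deposited tables of the inhibitor experiment hold FPKM, and no note says which tool made them. Their columns name the group of a sample but not the sample. Obstructed kidney with UNC569 has 7 columns for 8 samples, and ligated liver with UNC569 has 4 columns for 6 samples. Read depth behind the FPKM values is unknown, so the counting error of low genes cannot be given. FPKM was compared only within a tissue. Of the gene identifiers, 99.6% of 31054 in the counts and 94.9% of 38277 in the FPKM tables had a match in the mouse annotation.

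Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors and quasi-likelihood F tests on a model with 1 term per group, for 16162 genes in kidney and 13492 in liver. Genes with an FPKM of at least 1 in at least 3 libraries were tested with limma 3.58.1 on log2(FPKM + 1) with an intensity trend, 15338 in kidney, 12986 in liver and 15935 in lung. In each tissue the 4 groups shared 1 fit, with contrasts for injury, for genotype label or UNC569 after injury and after sham surgery, and for the difference between those responses. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene passed at an adjusted p under 0.05. These p-values measure spread between these libraries only. Printed CPM are TMM-normalised, and their logs used a prior count of 2.

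Fixed lists of marker genes, 43 in number, were tested with camera of limma at a preset correlation of 0.01 between genes and adjusted over the lists of a comparison. Genes, lists, tests and first alternatives were fixed before the data were examined. Named genes are the TAM receptors and ligands; the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 32 CPM or 10 FPKM and groups that do not overlap; and, from lists described, members with the smallest p. For sham and difference tests the 5 genes with the smallest p stand in place of the last 2 parts. Some genes that these rules pick, and a test that needs such a gene, are not reported here. Genes with fewer than 3 counts in a group are given as levels. Injury sets held the 200 genes with the largest rise and the 200 with the largest fall in the other experiment.

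The alternatives were DESeq2 1.42.0, RLE factors, no filter, a pseudocount of 0.1, median-of-ratios scaling, a block for replicate number, the estimated correlation, other set sizes and windows, and each library left out in turn. Libraries noted by the submitters to have a bad fastq file were also left out. Leaving out sham WT 1 and UUO WT 1, with or without sham WT 3, leaving out BDL KO 1 and BDL KO 3, averaging a close pair of lung libraries and adding a cardiac muscle covariate were chosen after the data were seen. Real labels were also exchanged between the 2 groups of each comparison, in all splits or at most 100.

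In simulated data, 100 genes changed 2-fold and as many 4-fold (99 in the knockout experiment). Of those, edgeR recovered 76% and 94.9% in kidney and 83% and 97.0% in liver, and limma 82% and 98% in kidney, 47% and 84% in liver and 84% and 100% in lung. False calls numbered 6, 11, 10, 7 and 15 in that order (DESeq2 26 in kidney and 19 in liver). The contrast with no change had 0 (DESeq2 3 and 1). These rates hold for simulated libraries and need not hold for real ones.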

Results

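RNA-seq libraries were prepared from mouse kidney, liver and lung in 2 experiments on MERTK, a receptor tyrosine kinase through which macrophages take up dying cells. In the knockout experiment, wild-type mice and mice labelled Mertk knockout had unilateral ureteral obstruction (UUO), which scars the kidney, bile duct ligation (BDL), which scars the liver, or sham surgery. Each of the 8 groups had 4 libraries. In the inhibitor experiment, mice received UNC569, an inhibitor of MERTK, or its solvent DMSO after UUO, BDL, lung bleomycin or sham treatment, in groups of 3 to 8 samples. The comparisons address which genes each injury changes and how the genotype label or UNC569 alters that response. Levels are group means ± SD, as TMM-normalised CPM in the knockout experiment and as deposited FPKM in the inhibitor experiment. Changes are log2 fold changes ± SE, written "log2". Adjusted p-values of genes are from edgeR in the knockout and limma in the inhibitor experiment. For genes that passed between 2 groups, all libraries of the second lay beyond every library of the first unless a lower number is given ("1 of 4 beyond"). Members of gene lists are counted as past over all genes, and as adjusted over the list alone where those counts differ. Lists were tested with camera at a preset correlation, and again with a correlation estimated from the data ("if estimated").

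Mertk (ENSMUSG00000014361, GRCm38 chromosome 2, 128698956 to 128802894, plus strand) was not lower in kidney libraries labelled knockout. In sham kidney its level was 34.1, 81.5, 48.9 and 70.3 CPM in the wild-type libraries and 83.3, 80.5, 83.8 and 61.0 CPM in those labelled knockout. In obstructed kidney the values were 33.8, 47.2, 55.2 and 59.2 CPM in wild type and 47.9, 53.5, 57.7 and 40.5 CPM under the knockout label. Sham liver held 18.1, 10.5, 14.8 and 13.8 CPM in wild type and 20.5, 10.8, 13.4 and 18.3 CPM under the knockout label. Only ligated liver differed in every library, with 21.3, 24.9, 28.3 and 28.4 CPM in wild type and 9.24, 17.6, 6.95 and 18.8 CPM under the knockout label. The log2 fold change by label was 0.39 ± 0.25 in sham kidney (adjusted p = 0.422, 2 of 4 beyond), 0.03 ± 0.25 in UUO kidney (adjusted p = 0.974, 0 of 4 beyond), 0.14 ± 0.29 in sham liver (adjusted p = 1, 2 of 4 beyond) and -0.97 ± 0.29 in BDL liver (adjusted p = 0.0614, 4 of 4 beyond). The BDL difference passed without BDL WT 1 (adjusted p = 0.0463), BDL KO 2 (0.0309) or BDL KO 4 (0.0299) and under DESeq2 (adjusted p = 0.0231). A knockout allele can leave a transcript that is counted over the whole gene, so these totals do not check the genotype, and groups are named here by their labels. In the inhibitor experiment Mertk ranged from 8.80 to 18.3 FPKM in kidney, 3.36 to 9.25 FPKM in liver and 8.26 to 16.1 FPKM in lung.

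**Figure D1:**
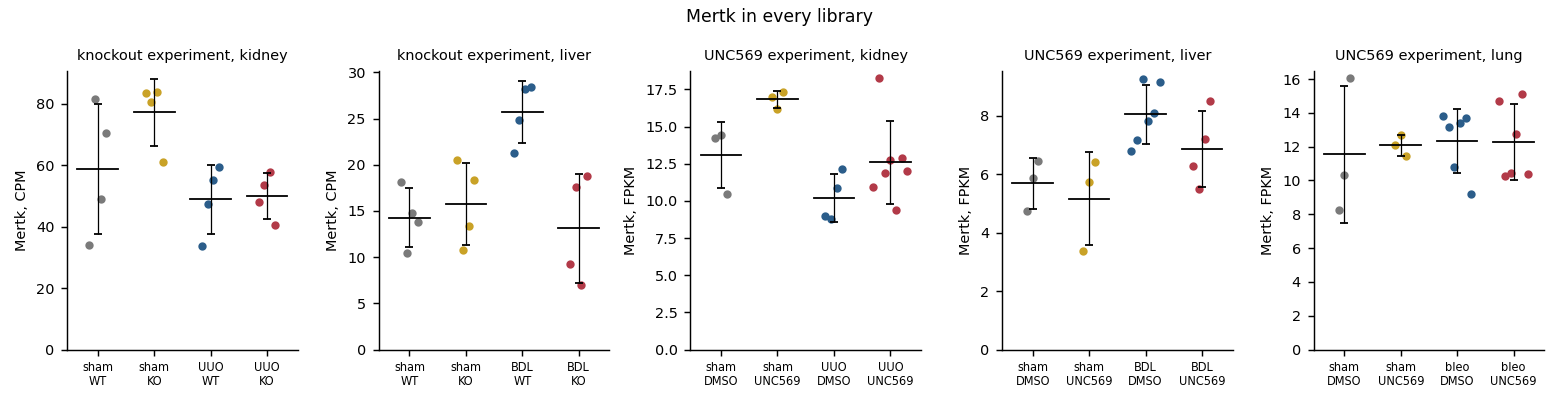
Mertk per library in the 5 sets of tissue and experiment, in CPM (knockout experiment) or FPKM (inhibitor experiment), with the mean ± SD of each group. Only in ligated liver do all 4 libraries labelled knockout lie outside the range of the wild-type libraries, below it.

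A pair of wild-type kidney libraries lacked tubule transcripts. In the library labelled sham WT 1, the proximal tubule list stood at 0.00313 of the other sham wild-type libraries, in median ratio, and the distal nephron list at 0.00424. Albumin (Alb) was 222140 CPM there and 0.273 to 119 CPM in the other kidney libraries. Across 15178 genes, which are not independent replicates, its rank correlation was 0.971 with the mean sham wild-type liver and 0.729 with the mean of the other sham wild-type kidneys. In the library labelled UUO WT 1, the proximal tubule list stood at 0.0357 of the other UUO wild-type libraries and the podocyte list at 0.451. The adipokine Adipoq was 825 CPM there and 8.96, 21.3 and 2.86 CPM in the other UUO wild-type libraries. Havcr1, which marks injured tubules, was 0.218 CPM in UUO WT 1 and 728, 539 and 301 CPM in the others. Both were kept as labelled, and counts without them were added after the data were seen.

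**Figure D2:**
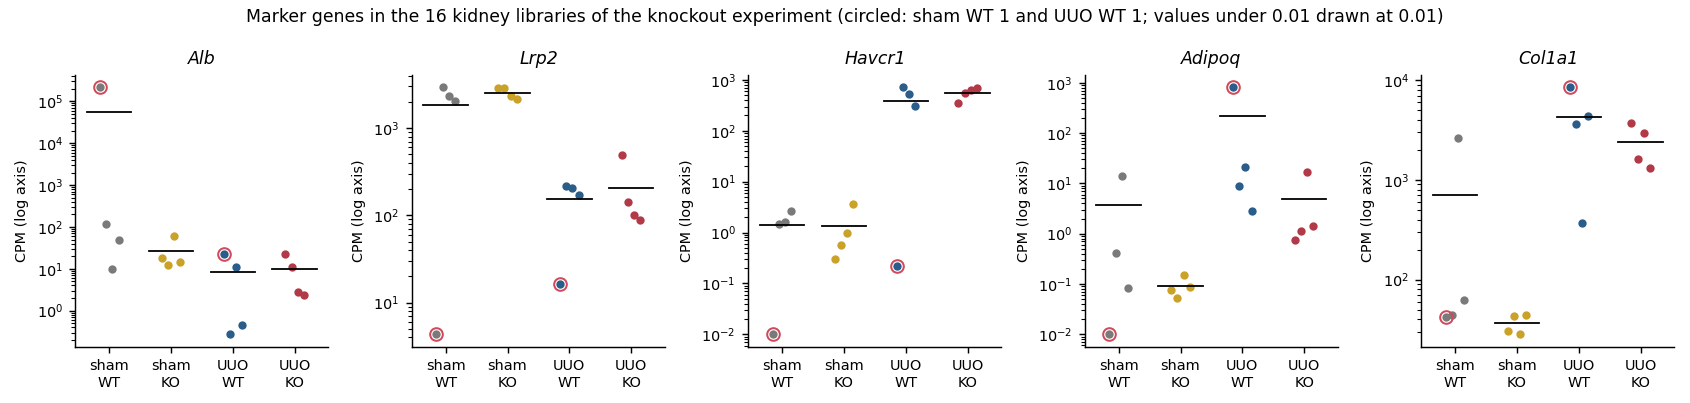
Alb, Lrp2, Havcr1, Adipoq and Col1a1 in each kidney library of the knockout experiment, in CPM on a log axis, with group means as lines and values under 0.01 drawn at 0.01. The circled sham WT 1 is high in Alb, and the circled UUO WT 1 is low in Lrp2 and Havcr1 and high in Adipoq.

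UUO in wild-type kidney raised genes of matrix, macrophages, inflammation and tubular injury and lowered genes of metabolism and the proximal tubule (4 against 4 libraries). Col15a1, a basement membrane collagen, rose (31.3 ± 11.8 to 325 ± 155 CPM, log2 3.37 ± 0.40, adjusted p = 5.84e-05), as did C1qa, a complement gene of tissue macrophages (15.1 ± 10.7 to 178 ± 58.2 CPM, log2 3.56 ± 0.51, adjusted p = 2.11e-04). Lcn2, an iron-binding protein released by injured tubules, rose (3.74 ± 1.27 to 219 ± 135 CPM, log2 5.86 ± 0.85, adjusted p = 2.17e-04). Ehhadh of peroxisomal fatty acid oxidation fell (1090.1 ± 312 to 62.0 ± 17.5 CPM, log2 -4.14 ± 0.47, adjusted p = 4.31e-05). By edgeR, 3243 genes were higher and 2842 lower of 16162 tested, and 3828 higher and 2623 lower without sham WT 1 and UUO WT 1.

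Of 34 extracellular matrix and fibroblast genes, 22 rose and 0 fell (24 and 0 adjusted over the list alone, median log2 2.40, camera adjusted p = 1.28e-08, adjusted p = 0.304 if estimated). Of 21 macrophage genes, 19 rose and 0 fell (20 and 0 adjusted over the list alone, median log2 3.03, camera adjusted p = 1.38e-09, adjusted p = 0.203 if estimated). Of 23 genes of inflammation and NF-kB, 19 rose and 1 fell (median log2 2.51, camera adjusted p = 4.76e-08, adjusted p = 0.202 if estimated). Of 20 genes of fatty acid oxidation, 0 rose and 15 fell (median log2 -2.01, camera adjusted p = 7.97e-08, adjusted p = 0.203 if estimated). Of 19 genes of oxidative phosphorylation, 0 rose and 17 fell (median log2 -1.23, camera adjusted p = 1.38e-09, adjusted p = 0.264 if estimated). Of 18 tubular injury genes, 11 rose and 0 fell (median log2 2.30, camera adjusted p = 5.94e-04, adjusted p = 0.282 if estimated). Without sham WT 1 and UUO WT 1 the medians of these lists kept their direction and call.

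Of 20 proximal tubule genes, 0 rose and 15 fell (0 and 20 adjusted over the list alone, median log2 -3.89, camera adjusted p = 9.26e-05, adjusted p = 0.460 if estimated). Distal nephron genes passed as a list only in 4 of 16 omissions (adjusted p up to 0.0419): 0 of 15 rose and 4 fell (median log2 -1.85, camera adjusted p = 0.0692). Of 21 efferocytosis genes, which hold the TAM receptors and ligands, 8 rose and 1 fell (8 and 2 adjusted over the list alone, median log2 0.83, camera adjusted p = 0.0191, adjusted p = 0.224 if estimated). The call was lost without sham WT 2 (adjusted p = 0.0583) or sham WT 4 (0.0594) or UUO WT 1 (0.0734). Sham WT 1 lacks tubule transcripts, and without sham WT 1 and UUO WT 1 the medians were -3.82 (camera adjusted p = 2.53e-13) for the proximal, -1.75 (camera adjusted p = 4.88e-06) for the distal and 1.35 (camera adjusted p = 0.0232) for the efferocytosis list. The TAM receptors Axl (log2 2.52 ± 0.31, adjusted p = 6.72e-05) and Tyro3 (log2 2.02 ± 0.51, adjusted p = 0.00685) rose. Mertk and the ligands Gas6 and Pros1 did not pass (log2 -0.27 to 0.83, adjusted p = 0.176 to 0.428), although Gas6 passed without sham WT 4 (adjusted p = 0.0312) and Pros1 without sham WT 1 (adjusted p = 6.30e-05).

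The largest falls by the fixed rule were liver genes whose sham mean came from the library labelled sham WT 1. Pzp, a plasma protease inhibitor, was 13500.1 CPM there and at most 99.6 CPM in any other kidney library. Apoh, Bhmt, C9, Hrg and Cyp4f14 were 4263, 1449, 886, 1656 and 598 CPM in that library, and C9 lost its call without it (adjusted p = 0.0566). Among the largest rises were the fibrillin gene Fbn2 (log2 7.96 ± 0.97, adjusted p = 6.88e-05) and the noncoding RNA Meg3 (log2 7.51 ± 1.37, adjusted p = 0.00102), which was 637 CPM in UUO WT 1 and at most 77.9 CPM in the other UUO wild-type libraries (log2 5.38 without sham WT 1 and UUO WT 1). Of 8 adipocyte genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone, median log2 5.47, camera adjusted p = 0.0626). The list passed in 4 of 16 omissions (adjusted p up to 0.0413). Adipocyte genes were high in UUO WT 1, and without sham WT 1 and UUO WT 1 the median was 1.20 (camera adjusted p = 0.295).

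In obstructed kidney, no gene passed between libraries labelled knockout and wild type (4 against 4; smallest edgeR adjusted p = 0.361). At an unadjusted p under 0.05 there were 2107 genes, and DESeq2 called 2 higher and 13 lower. The collagen gene Col1a1 was 4231 ± 3371 CPM in wild type and 2393 ± 1119 CPM under the knockout label (log2 -0.82 ± 1.15, adjusted p = 0.798), and the macrophage growth factor receptor gene Csf1r was 171 ± 56.6 CPM and 218 ± 55.6 CPM (log2 0.34 ± 0.45, adjusted p = 0.778). Macrophage genes rose as a list (median log2 0.61, camera adjusted p = 0.0107, adjusted p = 0.654 if estimated) with no member past the threshold. The call was lost without UUO WT 1 (adjusted p = 0.0810) or UUO WT 3 (0.0509). Genes of oxidative phosphorylation fell as a list (median log2 -0.75, camera adjusted p = 3.26e-09, adjusted p = 0.654 if estimated), also with no member past. Adipocyte genes fell as a list (median log2 -5.77, camera adjusted p = 9.69e-05, adjusted p = 0.654 if estimated), with 7 of 8 lower when adjusted over the list alone. The wild-type mean of Fabp4, a fatty acid binding protein, came from UUO WT 1 at 3994 CPM (log2 -4.46 ± 1.30, adjusted p = 0.361). Lists of extracellular matrix (median log2 0.04, camera adjusted p = 0.402), the TAM family (median log2 -0.35, camera adjusted p = 0.926), proximal tubule (median log2 0.37, camera adjusted p = 0.265) and tubular injury (median log2 0.18, camera adjusted p = 0.0513) did not pass. The matrix list had a mean of -0.13 against its positive median and upward test, and it passed without UUO WT 1 (camera adjusted p = 0.0265). Without the libraries with a noted bad fastq file it passed downward (median log2 -0.29, camera adjusted p = 0.0492). The tubular injury list passed in 8 of 16 omissions (adjusted p up to 0.0449). Axl, Tyro3, Gas6 and Pros1 did not pass (log2 -1.03 to 0.56, adjusted p = 0.385 to 0.951).

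In sham kidney, edgeR called 0 genes by genotype label (2842 at an unadjusted p under 0.05). DESeq2 called 43 higher and 407 lower. Without sham WT 4 edgeR called 1258 higher and 1391 lower, without sham KO 4 0 and 1, and without sham WT 1 and UUO WT 1 1 and 0. Of the lists, 10 of 31 passed (0 if estimated), among them matrix (median log2 -1.94, camera adjusted p = 1.22e-05, adjusted p = 0.716 if estimated), which lost its call without sham WT 3, and complement (median log2 -5.68, camera adjusted p = 1.38e-04, adjusted p = 0.716 if estimated), with a median of -1.45 (camera adjusted p = 0.0168) without sham WT 1 and UUO WT 1. Mertk, Axl, Tyro3, Gas6 and Pros1 did not pass (log2 -1.65 to 0.89, adjusted p = 0.158 to 0.945), and Gas6 and Pros1 passed without sham WT 4 (adjusted p = 0.0240 and 0.0193). The test of whether the UUO response differed by label gave 0 genes by edgeR (4146 at an unadjusted p under 0.05), 1259 higher and 685 lower by DESeq2, and 1639 higher and 1841 lower by edgeR without sham WT 4. Here 7 of 31 lists passed (0 if estimated), among them oxidative phosphorylation (median log2 -1.08, camera adjusted p = 1.89e-05, adjusted p = 0.808 if estimated) and matrix (median log2 2.16, camera adjusted p = 0.00150, adjusted p = 0.808 if estimated), the latter not without sham WT 3 or UUO WT 3. The same 5 genes did not pass (log2 -1.60 to 2.21, adjusted p = 0.0891 to 0.544), although Gas6 and Pros1 passed without sham WT 4 (adjusted p = 0.0106 and 0.0175).

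BDL in wild-type liver raised genes of matrix, macrophages, neutrophils and bile duct epithelium and lowered genes of fatty acid oxidation (4 against 4 libraries). The collagen gene Col1a2 rose (16.2 ± 6.44 to 197 ± 101 CPM, log2 3.604 ± 0.45, adjusted p = 8.26e-05), as did Trem2, a receptor of lipid-laden macrophages (0.495 ± 0.131 to 13.9 ± 5.42 CPM, log2 4.79 ± 0.69, adjusted p = 2.29e-04). Spp1, the secreted protein osteopontin, rose (42.8 ± 15.0 to 1307 ± 718 CPM, log2 4.93 ± 0.70, adjusted p = 2.16e-04). Slco1a1, a hepatocyte transporter of organic anions, fell (512 ± 58.1 to 10.5 ± 10.3 CPM, log2 -5.61 ± 0.55, adjusted p = 1.75e-05). By edgeR, 2203 genes were higher and 1724 lower of 13492 tested, and 3086 higher and 2865 lower when BDL KO 1 and BDL KO 3 were left out of the shared estimate of spread.

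Of 32 extracellular matrix genes, 28 rose and 0 fell (median log2 2.26, camera adjusted p = 7.94e-17, adjusted p = 0.231 if estimated). Of 18 genes of TGF-beta, the main fibrogenic cytokine, 10 rose and 0 fell (11 and 0 adjusted over the list alone, median log2 1.22, camera adjusted p = 4.12e-04, adjusted p = 0.156 if estimated). Of 21 macrophage genes, 20 rose and 0 fell (21 and 0 adjusted over the list alone, median log2 2.60, camera adjusted p = 2.91e-11, adjusted p = 0.237 if estimated). Of 9 genes of resident Kupffer cells, 6 rose and 0 fell (median log2 1.61, camera adjusted p = 0.00662, adjusted p = 0.509 if estimated). Of 9 neutrophil genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone, median log2 3.19, camera adjusted p = 4.84e-04, adjusted p = 0.289 if estimated). Of 20 genes of cholangiocytes and the ductular reaction, 14 rose and 0 fell (15 and 0 adjusted over the list alone, median log2 3.51, camera adjusted p = 1.48e-07, adjusted p = 0.237 if estimated). Of 20 fatty acid oxidation genes, 2 rose and 14 fell (median log2 -1.09, camera adjusted p = 2.73e-06, adjusted p = 0.238 if estimated).

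Of 20 hepatocyte genes, 1 rose and 5 fell (median log2 -0.54, camera adjusted p = 0.0169, adjusted p = 0.653 if estimated). The cytochrome P450 gene Cyp2e1 fell (log2 -1.89 ± 0.31, adjusted p = 5.57e-04). That list lost its call without BDL WT 3 (camera adjusted p = 0.162). Of 18 bile acid genes, 3 rose and 5 fell (3 and 7 adjusted over the list alone, median log2 -0.66, camera adjusted p = 0.0499, adjusted p = 0.653 if estimated), a call lost in 10 of 16 omissions (adjusted p up to 0.0761). Cyp8b1 (log2 -4.58 ± 0.78, adjusted p = 7.28e-04) and Cyp7b1 (log2 -3.33 ± 0.43, adjusted p = 1.06e-04), enzymes of bile acid synthesis, fell. Of 19 TAM and efferocytosis genes, 11 rose and 1 fell (11 and 2 adjusted over the list alone, median log2 1.16, camera adjusted p = 6.81e-04, adjusted p = 0.114 if estimated). Axl, Gas6 and Pros1 rose (log2 1.61 to 2.04, adjusted p = 0.00134 to 0.00226). Mertk rose (log2 0.85 ± 0.29, adjusted p = 0.0391) but lost its call in 7 of 16 omissions (adjusted p up to 0.108). Tyro3 did not pass (log2 0.43 ± 0.76, adjusted p = 0.7004).

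The largest rises included Lcn2 (log2 8.20 ± 1.11, adjusted p = 1.50e-04), the metal-binding protein gene Mt1 (log2 6.61 ± 1.08, adjusted p = 5.82e-04) and the macrophage gene Gpnmb (log2 8.19 ± 1.01, adjusted p = 7.30e-05). The largest falls were Hsd3b5, a steroid enzyme of male liver (279.9 ± 72.8 to 0.0210 ± 0.0420 CPM, adjusted p = 2.24e-09), and the major urinary protein genes Mup7, Mup11, Mup15 and Mup17 (log2 -10.06 to -8.72, adjusted p = 1.35e-06 to 1.48e-04). Mup genes are near-identical in sequence, so reads may not be assigned to the right member.

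In ligated liver, matrix, macrophage, interferon and bile duct gene lists were lower under the knockout label (4 against 4 libraries). These list calls end if estimated. Vim, an intermediate filament protein of mesenchymal cells, fell (103 ± 28.5 to 33.3 ± 19.3 CPM, log2 -1.63 ± 0.35, adjusted p = 0.0384), as did the collagen gene Col3a1 (347 ± 272 to 71.6 ± 43.03 CPM, log2 -2.28 ± 0.59, adjusted p = 0.0433). The monocyte receptor gene Ccr2 fell (31.01 ± 27.96 to 3.52 ± 3.84 CPM, log2 -3.13 ± 0.74, adjusted p = 0.0394), and so did Spp1 (1307 ± 718 to 150.3 ± 149.6 CPM, log2 -3.12 ± 0.64, adjusted p = 0.0370). The interferon-induced gene Ifit1 fell (12.3 ± 10.8 to 2.58 ± 1.32 CPM, log2 -2.26 ± 0.59, adjusted p = 0.0445). Col6a3, Vcam1 and the macrophage gene Mpeg1 also fell (log2 -1.92 to -1.71, adjusted p = 0.0384 to 0.0494). The largest rises were Depp1, Dact2, Irf2bp2, Rcl1, Tle1 and Atg2a, which acts in autophagy (log2 1.62 to 3.104, adjusted p = 0.0370 to 0.0419).

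Of 32 matrix genes, 0 rose and 12 fell (0 and 19 adjusted over the list alone, median log2 -1.18, camera adjusted p = 1.01e-07, adjusted p = 0.703 if estimated). Of 21 macrophage genes, 0 rose and 3 fell (1 and 12 adjusted over the list alone, median log2 -1.25, camera adjusted p = 4.25e-08, adjusted p = 0.703 if estimated). The mean log2 level of that list in BDL KO 2 (4.91) lay within wild type (4.78 to 5.84), and BDL KO 1 was lowest (1.99). Kupffer cell genes fell as a list only: 0 of 9 rose and 0 fell (0 and 5 adjusted over the list alone, median log2 -1.15, camera adjusted p = 3.79e-04, adjusted p = 0.703 if estimated). Of 19 interferon genes, 0 rose and 4 fell (0 and 14 adjusted over the list alone, median log2 -1.92, camera adjusted p = 1.01e-06, adjusted p = 0.703 if estimated). Their mean level was 5.29 in BDL WT 3, 2.49 to 3.40 in the other wild-type libraries and 0.96 to 2.64 under the knockout label. No single omission ended the call. Of 20 cholangiocyte genes, 0 rose and 3 fell (0 and 11 adjusted over the list alone, median log2 -1.56, camera adjusted p = 1.09e-06, adjusted p = 0.703 if estimated). Genes of the unfolded protein response and stress rose as a list: 2 of 16 rose and 1 fell (8 and 2 adjusted over the list alone, median log2 1.26, camera adjusted p = 0.00345, adjusted p = 0.703 if estimated), with the stress gene Trib3 higher (log2 2.17 ± 0.52, adjusted p = 0.0394, 3 of 4 beyond) and the heat shock gene Hspa1b lower (log2 -2.08 ± 0.49, adjusted p = 0.0394). Without BDL KO 1 and BDL KO 3 the median was -0.92 (camera adjusted p = 2.46e-07) for macrophage, -0.53 (camera adjusted p = 0.0153) for Kupffer cell and 0.28 (camera adjusted p = 0.234) for stress genes, whose call ended.

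Endothelial genes (median log2 -0.22, camera adjusted p = 0.798) and stellate cell genes (median log2 0.09, camera adjusted p = 0.827) did not pass as lists, although Ecm1, a matrix protein of stellate cells, rose (log2 1.24 ± 0.30, adjusted p = 0.0409, 3 of 4 beyond). Nor did hepatocyte genes (median log2 0.48, camera adjusted p = 0.0852), which passed without BDL WT 1 (adjusted p = 0.0441) or BDL WT 2 (0.0263) or BDL WT 4 (0.0488) or BDL KO 3 (0.00254). TAM and efferocytosis genes did not pass as a list (median log2 0.04, camera adjusted p = 0.380), with a mean of -0.21 and a downward test against a positive median. Axl, Tyro3, Gas6 and Pros1 did not pass (log2 -1.34 to 0.53, adjusted p = 0.0517 to 0.978), and Axl passed without BDL WT 1 (adjusted p = 0.0257) or BDL KO 2 (0.0135) or BDL KO 4 (0.0487).

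By edgeR, 360 genes were higher and 232 lower of 13492 tested. The count fell to 0 when any of the 8 sham libraries, BDL WT 2, BDL WT 3 or BDL WT 4 was left out, and was 0 higher and 1 lower without BDL KO 1 and 1 and 0 without BDL KO 3. It was 920 higher and 643 lower without BDL WT 1, 981 and 940 without BDL KO 2 and 900 and 534 without BDL KO 4. Each called gene above lost its call in 13 of 16 omissions, except Mpeg1 with 14. The smallest adjusted p over all genes was 0.0370. Without BDL KO 1 and BDL KO 3, which both have a noted bad fastq file, edgeR called 3 higher and 1 lower, and without all libraries so noted 0 higher and 0 lower. DESeq2 called 1046 higher and 862 lower in all libraries.

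In sham liver, edgeR and DESeq2 called 0 genes by genotype label (70 at an unadjusted p under 0.05 in edgeR), while 6 of 32 lists passed (0 if estimated). Mertk, Axl, Tyro3, Gas6 and Pros1 did not pass (log2 -0.39 to 0.14, adjusted p = 1). Whether the BDL response differed by label was tested directly, with 0 genes past by edgeR (1952 at an unadjusted p under 0.05) and 93 higher and 53 lower by DESeq2. Without BDL WT 1 edgeR called 38 higher and 6 lower, and without BDL KO 2 6 and 16. The same 5 genes did not pass (log2 -1.40 to 0.50, adjusted p = 0.269 to 0.888). In that test 9 of 32 lists passed (0 if estimated), among them matrix (median log2 -1.23, camera adjusted p = 2.19e-09, adjusted p = 0.755 if estimated) and macrophage genes (median log2 -1.25, camera adjusted p = 2.61e-06, adjusted p = 0.755 if estimated).

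In the inhibitor experiment, UUO in DMSO-treated kidney raised genes of matrix, macrophages, inflammation, cell division and tubular injury and lowered genes of the nephron and of metabolism (4 UUO against 3 sham libraries). Col1a1, a main fibrillar collagen of scars, rose (6.66 ± 1.67 to 196 ± 42.02 FPKM, log2 4.68 ± 0.41, adjusted p = 5.23e-08). C1qa (57.1 ± 9.15 to 698 ± 100.1 FPKM, log2 3.59 ± 0.22, adjusted p = 1.66e-09) and Havcr1 (0.800 ± 0.461 to 190.0 ± 45.3 FPKM, log2 6.72 ± 0.25, adjusted p = 5.12e-12) rose. The endocytic receptor gene Lrp2 of the proximal tubule fell (92.1 ± 13.7 to 8.40 ± 2.64 FPKM, log2 -3.35 ± 0.30, adjusted p = 7.81e-08). By limma, 4560 genes were higher and 3957 lower of 15338 tested. On the log2(FPKM + 1) scale used, changes of genes near 0 are understated.

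Of 33 matrix genes, 32 rose and 0 fell (median log2 2.65, camera adjusted p = 2.06e-11, adjusted p = 0.276 if estimated). Of 20 macrophage genes, 19 rose and 0 fell (20 and 0 adjusted over the list alone, median log2 2.88, camera adjusted p = 1.06e-12, adjusted p = 0.0867 if estimated). Of 21 inflammatory genes, 21 rose and 0 fell (median log2 2.56, camera adjusted p = 2.37e-10, adjusted p = 0.0427 if estimated). Of 19 cell cycle genes, 18 rose and 0 fell (19 and 0 adjusted over the list alone, median log2 1.33, camera adjusted p = 9.59e-06, adjusted p = 0.213 if estimated). Of 18 tubular injury genes, 17 rose and 0 fell (median log2 2.87, camera adjusted p = 1.75e-11, adjusted p = 0.00429 if estimated). Of 20 fatty acid oxidation genes, 1 rose and 16 fell (median log2 -1.54, camera adjusted p = 1.06e-06, adjusted p = 0.213 if estimated). Of 19 oxidative phosphorylation genes, 0 rose and 19 fell (median log2 -2.21, camera adjusted p = 1.82e-11, adjusted p = 0.0867 if estimated).

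Of 20 proximal tubule genes, 0 rose and 20 fell (median log2 -4.33, camera adjusted p = 2.06e-11, adjusted p = 0.213 if estimated). Of 15 distal nephron genes, 0 rose and 12 fell (0 and 13 adjusted over the list alone, median log2 -2.37, camera adjusted p = 1.22e-06, adjusted p = 0.0867 if estimated). Of 18 efferocytosis genes, 13 rose and 3 fell (median log2 0.86, camera adjusted p = 0.0198, adjusted p = 0.296 if estimated). Axl, Tyro3 and Pros1 rose (log2 1.11 to 2.41, adjusted p = 2.51e-07 to 7.49e-05). Gas6 fell (log2 -0.40 ± 0.14, adjusted p = 0.0202) and lost its call without sham DMSO 2 (adjusted p = 0.114) or UUO DMSO 2 (0.0612) or UUO DMSO 3 (0.0539), and Mertk did not pass (log2 -0.33 ± 0.18, adjusted p = 0.135). Further large rises were Aoc1 and Col12a1 (log2 5.56 to 5.80, adjusted p = 5.12e-12 to 3.23e-06). Sprr2f, of a family whose near-identical members share reads, was listed at 0 in sham and at 45.7 ± 11.7 FPKM in UUO. Further large falls were Miox, Ces1f, Azgp1 and Slc22a7 (log2 -5.97 to -5.17, adjusted p = 2.97e-08 to 2.86e-06).

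In obstructed kidney, Upk1a and Vim were lower and Gas6 higher with UNC569 (7 UNC569 against 4 DMSO libraries). The uroplakin gene Upk1a, expressed in the lining of the urinary tract, fell (32.8 ± 9.06 to 7.20 ± 3.58 FPKM, log2 -2.14 ± 0.35, adjusted p = 0.0102), as did Upk3a, Upk2 and Upk1b (log2 -2.69 to -2.32, adjusted p = 0.0121 to 0.0477). Vim fell (468 ± 53.01 to 235 ± 104 FPKM, log2 -1.09 ± 0.23, adjusted p = 0.0333), as did Col4a1 of basement membrane (log2 -0.61 ± 0.14, adjusted p = 0.0405). Of 33 matrix genes, 0 rose and 2 fell (median log2 -0.67, camera adjusted p = 1.33e-06, adjusted p = 0.737 if estimated). The mean level of that list was low in UUO UNC569 4 and 5 (4.53 and 4.37 log2), while UUO UNC569 0 and 2 (6.25 and 6.32) lay above all DMSO libraries (5.72 to 6.18). The matrix list also fell with UNC569 in sham kidney (median log2 -0.56, camera adjusted p = 5.64e-05, adjusted p = 0.624 if estimated), and it did not pass for the difference in UUO response (median log2 0.01, camera adjusted p = 0.559). Gas6 rose (131 ± 16.2 to 185 ± 19.5 FPKM, log2 0.49 ± 0.11, adjusted p = 0.0405). S100a9, a neutrophil gene, rose (3.601 ± 2.15 to 14.9 ± 6.16 FPKM, log2 1.86 ± 0.43, adjusted p = 0.0426), as did S100a8 (log2 1.75 ± 0.40, adjusted p = 0.0420). Of 5 neutrophil genes, 2 rose and 0 fell (median log2 0.81, camera adjusted p = 0.00305, adjusted p = 0.198 if estimated). Slc12a1, a salt transporter of the thick ascending limb, rose (log2 1.27 ± 0.21, adjusted p = 0.0109).

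Of 10 MHC class II and dendritic cell genes, 0 rose and 1 fell (0 and 5 adjusted over the list alone, median log2 -0.50, camera adjusted p = 5.72e-04, adjusted p = 0.609 if estimated). Ciita, the switch for these genes, fell (log2 -0.69 ± 0.16, adjusted p = 0.0477). This list fell in sham kidney too (median log2 -0.73, camera adjusted p = 5.64e-05, adjusted p = 0.282 if estimated). Of 19 cell cycle genes, 0 rose and 0 fell (0 and 3 adjusted over the list alone, median log2 -0.43, camera adjusted p = 2.97e-04, adjusted p = 0.651 if estimated). Adipocyte genes fell as a list (median log2 -0.85, camera adjusted p = 5.89e-04, adjusted p = 0.609 if estimated), with no member past over all genes. Macrophage genes (median log2 -0.15, camera adjusted p = 0.205) did not pass as a list in all libraries but did without UUO DMSO 0 (adjusted p = 0.0224) or UUO DMSO 1 (0.0174). Nor did the lists of efferocytosis (median log2 -0.18, camera adjusted p = 0.354), proximal tubule (median log2 -0.18, camera adjusted p = 0.696) and tubular injury (median log2 -0.02, camera adjusted p = 0.948), although the chaperone gene Clu fell (log2 -0.89 ± 0.20, adjusted p = 0.0405). The proximal tubule list passed without UUO DMSO 2 (camera adjusted p = 0.00967). Mertk, Axl, Tyro3 and Pros1 did not pass (log2 -0.46 to 0.27, adjusted p = 0.152 to 0.725). Further large rises were Slc15a2, Bbs2, Bckdhb and Zcchc7 (log2 0.76 to 1.12, adjusted p = 0.0254 to 0.0477), and further large falls Car3 and Sptssb (log2 -2.76 to -2.00, adjusted p = 0.0303 to 0.0326).

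By limma, 38 genes were higher and 161 lower of 15338 tested, and 7 higher and 39 lower with a pseudocount of 0.1. The count was 0 higher and 7 lower without UUO DMSO 1, 7 and 27, 1 and 33 and 11 and 63 without UUO DMSO 0, 2 and 3, and 21 and 106 without sham UNC569 1. It was 3 and 37, 61 and 268, 8 and 68, 8 and 42 and 7 and 71 without UUO UNC569 1, 2, 3, 4 and 6. Upk1a, Upk3a and Slc12a1 lost their call only without UUO DMSO 1 (adjusted p = 0.0637, 0.0698 and 0.0637), and Bbs2 without UUO DMSO 1 (adjusted p = 0.0843) or UUO DMSO 2 (0.0935). The other called genes named lost it in 4 to 14 of 17 omissions (adjusted p up to 0.160).

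In sham kidney, UNC569 went with lower Hspb1 and Gadd45g and higher Igfbp1 and Dbp (3 against 3 libraries). The small heat shock protein gene Hspb1 fell (165 ± 43.99 to 25.7 ± 1.58 FPKM, log2 -2.60 ± 0.16, adjusted p = 9.53e-08), as did the stress sensor gene Gadd45g (log2 -3.27 ± 0.29, adjusted p = 1.93e-05). Igfbp1, which binds insulin-like growth factors, rose (3.27 ± 1.60 to 24.5 ± 4.32 FPKM, log2 2.63 ± 0.25, adjusted p = 2.94e-05), as did Tbcel and Slc35f3 (log2 1.11 to 2.32, adjusted p = 1.20e-04 to 1.43e-04). Dbp, a clock-controlled transcription factor chosen after its values were seen, was 32.9, 32.6 and 48.1 FPKM with DMSO and 343, 285 and 285 FPKM with UNC569. Axl fell (log2 -0.85 ± 0.26, adjusted p = 0.0287) and lost its call without sham DMSO 1 (adjusted p = 0.129) or sham UNC569 2 (0.154), while Mertk, Tyro3, Gas6 and Pros1 did not pass (log2 -0.44 to 0.35, adjusted p = 0.208 to 0.606). By limma, 2033 genes were higher and 928 lower, and the split turned to 1221 and 1636 under median-of-ratios scaling, which moved the median of all genes from 0.07 to -0.05. Without sham DMSO 1 the counts were 1077 and 520, without sham DMSO 2 1221 and 471 and without sham UNC569 2 1330 and 422. The test of whether the UUO response differed by UNC569 gave 947 higher and 2053 lower genes, 1586 and 1367 under median-of-ratios scaling (median of all genes -0.13 and 0.03), and 607 and 1356 without sham DMSO 1. Hspb1 (log2 2.89 ± 0.20, adjusted p = 7.22e-07), the chaperone gene Hsph1 (log2 2.20 ± 0.25, adjusted p = 1.59e-04) and Gas6 (log2 0.62 ± 0.18, adjusted p = 0.0270) passed upward. Rab43, Cmtm6 and Zbtb7a passed downward (log2 -1.58 to -1.40, adjusted p = 1.59e-04). The call of Gas6 was lost in 5 of 17 omissions (adjusted p up to 0.0830). Mertk, Axl, Tyro3 and Pros1 did not pass (log2 -0.14 to 0.40, adjusted p = 0.417 to 0.828).

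BDL in DMSO-treated liver raised genes of macrophages, bile duct epithelium, inflammation and matrix and lowered genes of hepatocyte metabolism (6 BDL against 3 sham libraries). Cd68 of macrophage lysosomes rose (6.12 ± 1.80 to 27.4 ± 9.12 FPKM, log2 1.96 ± 0.30, adjusted p = 5.70e-04), as did Spp1 (34.4 ± 21.5 to 366 ± 286 FPKM, log2 3.14 ± 0.58, adjusted p = 0.00247). Thbs1, a matrix glycoprotein, rose (0.0603 ± 0.0335 to 4.99 ± 2.59 FPKM, log2 2.38 ± 0.32, adjusted p = 2.33e-04), and Cyp2e1 fell (2989 ± 757 to 637 ± 317 FPKM, log2 -2.36 ± 0.38, adjusted p = 8.70e-04). By limma, 710 genes were higher and 1028 lower of 12986 tested. Under median-of-ratios scaling the split was 948 and 779, with the median of all genes at 0.02 in place of -0.10. Without sham DMSO 1 the counts were 284 and 530, and without sham DMSO 2 372 and 358.

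Of 21 macrophage genes, 14 rose and 0 fell (18 and 0 adjusted over the list alone, median log2 1.48, camera adjusted p = 2.68e-13, adjusted p = 0.206 if estimated). Gpnmb was listed at 0 in sham and at 7.93 ± 5.85 FPKM after BDL. Of 17 cholangiocyte genes, 11 rose and 0 fell (13 and 0 adjusted over the list alone, median log2 1.41, camera adjusted p = 8.68e-11, adjusted p = 0.206 if estimated). Of 20 inflammatory genes, 7 rose and 0 fell (median log2 1.01, camera adjusted p = 9.54e-08, adjusted p = 0.267 if estimated). Of 30 matrix genes, 9 rose and 0 fell (15 and 0 adjusted over the list alone, median log2 0.84, camera adjusted p = 7.12e-09, adjusted p = 0.304 if estimated). Col1a1 (log2 2.19 ± 0.53, adjusted p = 0.0131) and Col6a1 (log2 1.31 ± 0.31, adjusted p = 0.0116) rose. Of 20 fatty acid oxidation genes, 0 rose and 15 fell (0 and 16 adjusted over the list alone, median log2 -1.002, camera adjusted p = 9.07e-07, adjusted p = 0.310 if estimated). Hepatocyte genes did not pass as a list: 0 of 20 rose and 6 fell (median log2 -0.41, camera adjusted p = 0.0548), and the list passed without BDL DMSO 0 (adjusted p = 0.0407) or BDL DMSO 1 (0.0480) or BDL DMSO 2 (0.0413) or BDL DMSO 3 (0.0139). Of 18 bile acid genes, 1 rose and 5 fell (2 and 8 adjusted over the list alone, median log2 -0.60, camera adjusted p = 0.0348, adjusted p = 0.546 if estimated). The call was lost without sham DMSO 2 (adjusted p = 0.0605) or BDL DMSO 4 (0.0694) or BDL DMSO 5 (0.0709). Slco1a1 (log2 -6.81 ± 0.43, adjusted p = 9.87e-08) and Nr0b2, a nuclear receptor of the bile acid loop (log2 -1.50 ± 0.25, adjusted p = 0.00106), fell.

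Complement and acute phase genes (median log2 0.20, camera adjusted p = 0.127) did not pass as a list in all libraries but did without sham DMSO 0 (adjusted p = 2.09e-04) or BDL DMSO 0 (0.0494). Of 18 efferocytosis genes, 4 rose and 0 fell (median log2 0.46, camera adjusted p = 9.14e-04, adjusted p = 0.267 if estimated). Axl rose (log2 1.12 ± 0.26, adjusted p = 0.00937), while Mertk, Gas6 and Pros1 did not pass (log2 0.27 to 0.67, adjusted p = 0.149 to 0.574). Mertk passed under median-of-ratios scaling (adjusted p = 0.0435). Further large rises were Lrtm2 and Cib3 (log2 3.78 to 3.85, adjusted p = 6.77e-06 to 1.30e-05). The largest falls were Hsd3b5, Sult2a8, Car3 and the Mup genes Mup3 and Mup21 (log2 -8.91 to -6.95, adjusted p = 4.20e-08 to 1.17e-04), whose reads are not safely told apart. Without sham DMSO 1, Col6a1 and Axl lost their call (adjusted p = 0.0601 and 0.0696), and Col1a1 lost it without sham DMSO 0 (adjusted p = 0.0591) or sham DMSO 1 (0.0710).

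In ligated liver, MHC class II, early response, ductular and macrophage genes were lower with UNC569 (4 UNC569 against 6 DMSO libraries). Cd74, which guides assembly of MHC class II, fell (82.2 ± 53.3 to 15.6 ± 3.53 FPKM, log2 -2.10 ± 0.37, adjusted p = 0.0295), as did the class II genes H2-Ab1, H2-Aa and H2-Eb1 (log2 -2.43 to -2.24, adjusted p = 0.0272 to 0.0295), which share sequence. Fos, an early response transcription factor, fell (23.6 ± 15.0 to 2.47 ± 0.396 FPKM, log2 -2.60 ± 0.47, adjusted p = 0.0295), as did Cd24a (22.8 ± 11.4 to 4.71 ± 0.847 FPKM, log2 -1.95 ± 0.32, adjusted p = 0.0293) and the macrophage chemokine receptor gene Cx3cr1 (log2 -1.96 ± 0.39, adjusted p = 0.0483). Ccn1, a target of TGF-beta, fell (log2 -2.46 ± 0.50, adjusted p = 0.0483), and so did Thbs1 (log2 -1.65 ± 0.29, adjusted p = 0.0295). The integrin gene Itgb3 rose (log2 1.11 ± 0.23, adjusted p = 0.0483), as did Il1r1, Nfil3, Cux2, Arl13b, Fam222a and Dnajc12 (log2 1.40 to 2.01, adjusted p = 0.0293 to 0.0483).

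Of 6 MHC class II and dendritic cell genes, 0 rose and 4 fell (median log2 -2.17, camera adjusted p = 3.63e-10, adjusted p = 0.109 if estimated). Of 30 matrix genes, 0 rose and 1 fell (0 and 7 adjusted over the list alone, median log2 -0.61, camera adjusted p = 6.83e-12, adjusted p = 0.210 if estimated). The mean log2 level of that list was 2.20, 2.11 and 2.33 in BDL DMSO 0, 2 and 3, within the 1.68 to 2.41 with UNC569, and 3.26, 3.31 and 3.23 in BDL DMSO 1, 4 and 5. Of 17 TGF-beta genes, 0 rose and 2 fell (median log2 -0.30, camera adjusted p = 3.24e-06, adjusted p = 0.171 if estimated). Of 21 macrophage genes, 0 rose and 1 fell (0 and 11 adjusted over the list alone, median log2 -0.90, camera adjusted p = 2.06e-13, adjusted p = 0.171 if estimated). Inflammatory genes fell as a list only: 0 of 20 rose and 0 fell (0 and 6 adjusted over the list alone, median log2 -0.66, camera adjusted p = 2.87e-09, adjusted p = 0.171 if estimated). Of 15 early response genes, 0 rose and 2 fell (0 and 6 adjusted over the list alone, median log2 -0.55, camera adjusted p = 3.62e-08, adjusted p = 0.171 if estimated). Of 17 cholangiocyte genes, 0 rose and 1 fell (1 and 12 adjusted over the list alone, median log2 -0.94, camera adjusted p = 2.06e-13, adjusted p = 0.119 if estimated). Hepatocyte genes rose as a list only: 0 of 20 rose and 0 fell (1 and 0 adjusted over the list alone, median log2 0.46, camera adjusted p = 6.84e-04, adjusted p = 0.351 if estimated). So did neutrophil genes: 0 of 9 rose and 0 fell (median log2 0.59, camera adjusted p = 0.0394, adjusted p = 0.400 if estimated), a call lost in 5 omissions. Efferocytosis genes (median log2 -0.15, camera adjusted p = 0.389) and Mertk, Axl, Gas6 and Pros1 (log2 -0.93 to 0.44, adjusted p = 0.124 to 0.961) did not pass, Axl passing without BDL UNC569 2 (adjusted p = 0.0409).

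By limma, 16 genes were higher and 25 lower of 12986 tested, with 4 higher and 11 lower at a pseudocount of 0.1 and 1 higher and 0 lower without the filter on low values. Every library but BDL UNC569 2 and BDL DMSO 3 lowered the count when left out, to 0 without BDL UNC569 0, 1 or 3, 1 higher and 1 lower without BDL DMSO 4, and 7 and 5, 8 and 8, 9 and 13 and 8 and 18 without BDL DMSO 5, 1, 0 and 2. Without sham DMSO 1 and 2 it was 9 and 13 and 9 and 14, and without sham UNC569 0, 1 and 2 8 and 10, 8 and 12 and 9 and 11. It rose to 69 and 74 without BDL UNC569 2 and 49 and 67 without BDL DMSO 3. The called genes named lost their call in 3 to 14 of 16 omissions (adjusted p up to 0.236). In sham liver limma called 0 genes between UNC569 and DMSO (241 at an unadjusted p under 0.05; 2 higher and 0 lower without the filter), and Mertk, Axl, Gas6 and Pros1 did not pass (log2 -0.25 to 0.11, adjusted p = 1). Early response genes fell there as a list: 0 of 15 rose and 0 fell (0 and 3 adjusted over the list alone, median log2 -0.78, camera adjusted p = 2.77e-09, adjusted p = 0.285 if estimated). They did not pass as a list for the difference in BDL response (median log2 -0.29, camera adjusted p = 0.463), where 11 of 32 lists passed (0 if estimated). The difference in BDL response gave 0 genes (610 at an unadjusted p under 0.05; 0 higher and 1 lower without the filter), with the same 4 genes not past (log2 -1.04 to 0.69, adjusted p = 0.976 to 1.00).

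**Figure D3:**
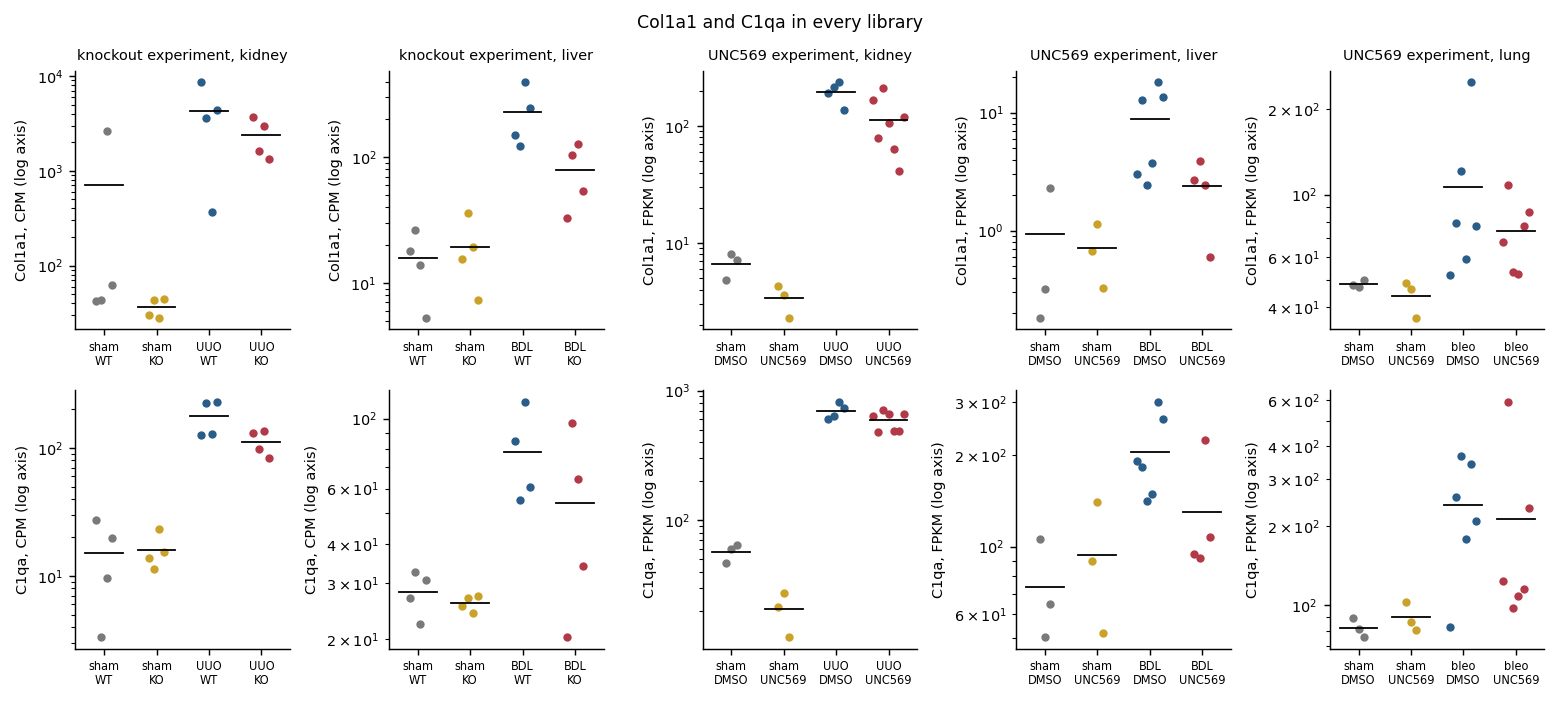
Col1a1 and C1qa per library in the 5 sets of tissue and experiment, in CPM or FPKM on a log axis, with group means. Injured kidney libraries of the inhibitor experiment lie above sham libraries in both genes.

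After bleomycin, which injures the alveoli, the elastin gene Eln was higher and the clock genes Per2 and Per3 lower in DMSO-treated lung (6 against 3 sham libraries). A difference in time of day, which no label gives, stays open. Eln rose (1.76 ± 0.544 to 17.6 ± 10.4 FPKM, log2 2.54 ± 0.43, adjusted p = 0.0287), as did Thbs1 (48.4 ± 18.96 to 151 ± 28.4 FPKM, log2 1.66 ± 0.29, adjusted p = 0.0380), the matrix gene Spon2 and the kinase gene Pim1 (log2 0.99 to 2.55, adjusted p = 0.0233). Per2, which closes the circadian feedback loop, fell (15.1 ± 1.76 to 4.24 ± 1.41 FPKM, log2 -1.66 ± 0.24, adjusted p = 0.0233), as did Per3 (log2 -1.95 ± 0.35, adjusted p = 0.0445). Ccdc191, Etfbkmt, Eef2k and Znrd1as also fell (log2 -2.69 to -0.72, adjusted p = 0.0233 to 0.0270). Cardiac muscle and fat transcripts varied between lungs: Myh6, a heart myosin, was 312, 328 and 1.08 FPKM in sham DMSO and 0 to 71.9 FPKM in bleomycin DMSO libraries.

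Of 33 matrix genes, 2 rose and 0 fell (23 and 3 adjusted over the list alone, median log2 0.86, camera adjusted p = 4.28e-12, adjusted p = 0.222 if estimated). Macrophage genes rose as a list only: 0 of 21 rose and 0 fell (12 and 0 adjusted over the list alone, median log2 0.90, camera adjusted p = 8.17e-08, adjusted p = 0.322 if estimated). So did inflammatory genes: 0 of 21 rose and 0 fell (10 and 0 adjusted over the list alone, median log2 0.67, camera adjusted p = 2.17e-08, adjusted p = 0.165 if estimated). Genes of the transitional state of alveolar repair rose as a list only: 0 of 12 rose and 0 fell (5 and 0 adjusted over the list alone, median log2 0.59, camera adjusted p = 4.99e-05, adjusted p = 0.322 if estimated). Airway genes fell as a list only: 0 of 12 rose and 0 fell (0 and 7 adjusted over the list alone, median log2 -1.11, camera adjusted p = 1.32e-05, adjusted p = 0.322 if estimated). Of 14 clock genes, 0 rose and 2 fell (2 and 8 adjusted over the list alone, median log2 -1.32, camera adjusted p = 1.05e-05, adjusted p = 0.173 if estimated). With a covariate for cardiac muscle, added after the data were seen, the airway median was -0.62 (camera adjusted p = 0.0315).

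Alveolar type 2 genes did not pass (median log2 0.03, camera adjusted p = 0.334). Adipocyte genes (median log2 -2.34, camera adjusted p = 0.00377, adjusted p = 0.374 if estimated) and cardiac muscle genes (median log2 -2.98, camera adjusted p = 4.25e-04, adjusted p = 0.348 if estimated) fell as lists. With the cardiac covariate those medians were 0.23 (camera adjusted p = 0.823) and -0.02 (camera adjusted p = 0.967). Mertk, Axl, Tyro3, Gas6 and Pros1 did not pass (log2 -0.31 to 0.55, adjusted p = 0.217 to 0.809). Tyro3 passed without sham DMSO 2 (adjusted p = 0.0295).

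By limma, 4 genes were higher and 7 lower of 15935 tested (3122 at an unadjusted p under 0.05), with 18 and 7 at a pseudocount of 0.1, 11 and 8 under median-of-ratios scaling, 0 and 1 with the close pair sham DMSO 0 and 1 averaged and 0 and 0 with the cardiac covariate. The counts were 646 and 1265 without sham DMSO 2, 158 and 84 without bleomycin DMSO 0 and 128 and 64 without bleomycin UNC569 1. They were 0 and 0 without sham DMSO 0, 0 and 2 without sham DMSO 1, 9 and 10 without sham UNC569 1, and 0 and 3, 0 and 0, 2 and 5 and 1 and 2 without bleomycin DMSO 1, 3, 4 and 5. Per2 lost its call without sham DMSO 0 (adjusted p = 0.220) or sham DMSO 1 (0.175) or bleomycin DMSO 3 (0.0557), and the other called genes named in 3 to 13 of 18 omissions (adjusted p up to 0.304).

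**Figure D4:**
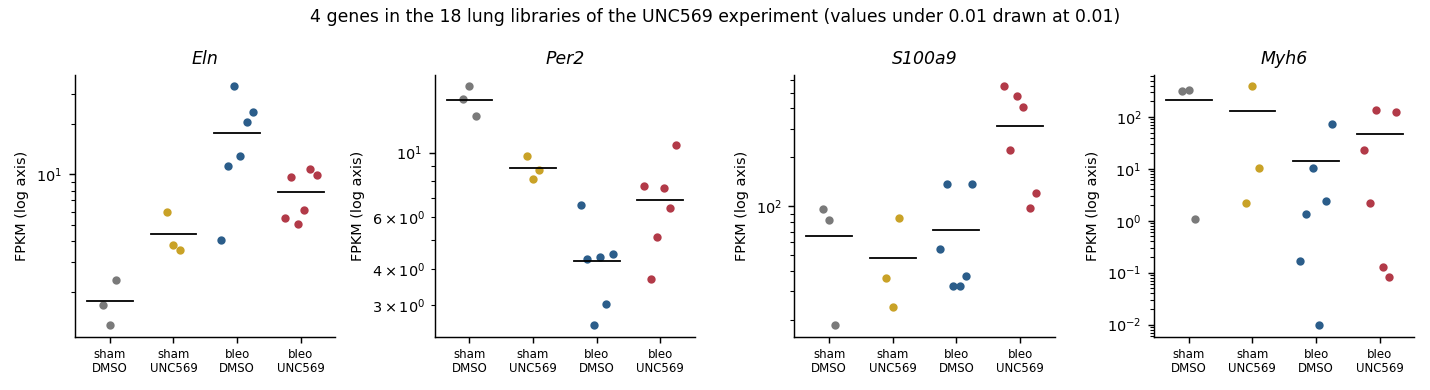
Eln, Per2, S100a9 and Myh6 in each lung library, in FPKM on a log axis, with group means. Eln is higher and Per2 lower in all 6 bleomycin DMSO libraries than in the 3 sham DMSO libraries, and Myh6 varies within groups.

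In bleomycin-injured lung, no single gene passed between UNC569 and DMSO (6 against 6 libraries), while lists moved. Neutrophil genes rose as a list: 0 of 11 rose and 0 fell (9 and 0 adjusted over the list alone, median log2 1.31, camera adjusted p = 2.06e-12, adjusted p = 0.0758 if estimated). S100a9 was 71.8 ± 51.1 FPKM with DMSO and 312 ± 191 FPKM with UNC569, and it and S100a8 did not pass over all genes (log2 1.60 to 2.11, adjusted p = 0.867). Matrix genes fell as a list (median log2 -0.42, camera adjusted p = 2.91e-08, adjusted p = 0.283 if estimated). Genes of TGF-beta (median log2 -0.30, camera adjusted p = 3.36e-08, adjusted p = 0.0758 if estimated) and of MHC class II and dendritic cells (median log2 -0.39, camera adjusted p = 2.91e-08, adjusted p = 0.0758 if estimated) fell as lists. Airway genes (median log2 0.59, camera adjusted p = 1.12e-05, adjusted p = 0.283 if estimated) rose as a list. Cardiac muscle genes rose as a list (median log2 1.18, camera adjusted p = 0.0239, adjusted p = 0.675 if estimated), a call lost in 5 of 18 omissions (adjusted p up to 0.249). Myh6 was 22.9, 2.21, 136, 0.129, 0.0814 and 123 FPKM in the bleomycin UNC569 libraries. Macrophage genes (median log2 -0.19, camera adjusted p = 0.0613), which passed in 5 of 18 omissions (adjusted p up to 0.0496), and efferocytosis genes (median log2 -0.02, camera adjusted p = 0.566) did not pass. Mertk, Axl, Tyro3, Gas6 and Pros1 did not pass (log2 -0.33 to 0.16, adjusted p = 0.867 to 0.993).

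The limma count in injured lung was 0 (843 genes at an unadjusted p under 0.05), and 0 higher and 1 lower without bleomycin UNC569 5. In sham lung, 6 of 32 lists passed (0 if estimated) and limma called 0 genes between UNC569 and DMSO (1206 at an unadjusted p under 0.05), 1 higher and 0 lower without the filter, 0 and 1 with sham DMSO 0 and 1 averaged, 0 and 1 without sham DMSO 1, 94 and 178 without sham DMSO 2 and 3 and 0 without sham UNC569 2. Mertk, Axl, Tyro3, Gas6 and Pros1 did not pass (log2 -0.28 to 0.17, adjusted p = 0.810 to 0.949). The difference in bleomycin response passed in 19 of 32 lists (0 if estimated) and 0 genes (1893 at an unadjusted p under 0.05), 1 higher and 0 lower with sham DMSO 0 and 1 averaged, 1 and 0 without sham DMSO 1, 408 and 283 without sham DMSO 2 and 1 and 0 without bleomycin UNC569 2. The same 5 genes did not pass (log2 -0.50 to 0.44, adjusted p = 0.550 to 0.909).

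Whether UNC569 or the knockout label reversed each injury was tested on the genes that injury changed most in the other experiment. In ligated liver, the 129 tested genes of the rise set had a median log2 fold change of -0.71 with UNC569 (camera adjusted p = 7.26e-19, adjusted p = 0.300 if estimated). Under the knockout label the 187 genes had -0.56 (camera adjusted p = 2.97e-06, adjusted p = 0.546 if estimated). The sets that fell in liver injury had 0 with UNC569 (camera adjusted p = 0.0832) and -0.33 under the knockout label (camera adjusted p = 0.0137, adjusted p = 0.712 if estimated). The label value was -0.0315 (camera adjusted p = 0.504) without BDL KO 1 and BDL KO 3. In obstructed kidney the rise set had -0.22 with UNC569 (camera adjusted p = 0.0260, adjusted p = 0.577 if estimated), and 0.20 under the knockout label (camera adjusted p = 0.00129, adjusted p = 0.546 if estimated). The kidney sets that fell had 0.04 and 0.05 (camera adjusted p = 0.118 and 0.519). The former came from wild-type kidney, whose largest falls were liver genes of sham WT 1, so it cannot test reversal. The label value passed downward at -0.82 (camera adjusted p = 0.0136) without UUO KO 1, and at -0.07 (0.00476) without UUO WT 1, and upward at 0.67 (0.00344) without UUO WT 3 and 0.27 (0.0161) without UUO KO 3. For lung, genes changed by bleomycin in DMSO libraries 3 to 5 were tested in UNC569 against DMSO libraries 0 to 2. The 5 genes that rose had -0.31 (camera adjusted p = 0.0137, adjusted p = 0.512 if estimated) and the 6 that fell 0.20 (camera adjusted p = 0.0451, adjusted p = 0.577 if estimated).

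Across 11565 genes in ligated liver, which are not independent replicates, the effects of the knockout label and of UNC569 correlated with r = 0.492 (jackknife SE 0.161, rho = 0.474), and 66.4% shared a sign. Without BDL KO 1 and BDL KO 3, r was 0.248. In obstructed kidney r was -0.0172 (jackknife SE 0.1998, rho = -0.0721). The injury effects themselves correlated with r = 0.696 (jackknife SE 0.0989) in kidney and 0.731 (jackknife SE 0.0676) in liver between the experiments. Within 10 Mb of Mertk, where a knockout line can keep variants of its founder strain, 9 of 181 genes passed in ligated liver (4.97%), against 579 of 13300 elsewhere (4.35%, Fisher's exact test, two-sided, p = 0.585). The other knockout comparisons had 0 called genes to place.

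**Figure D5:**
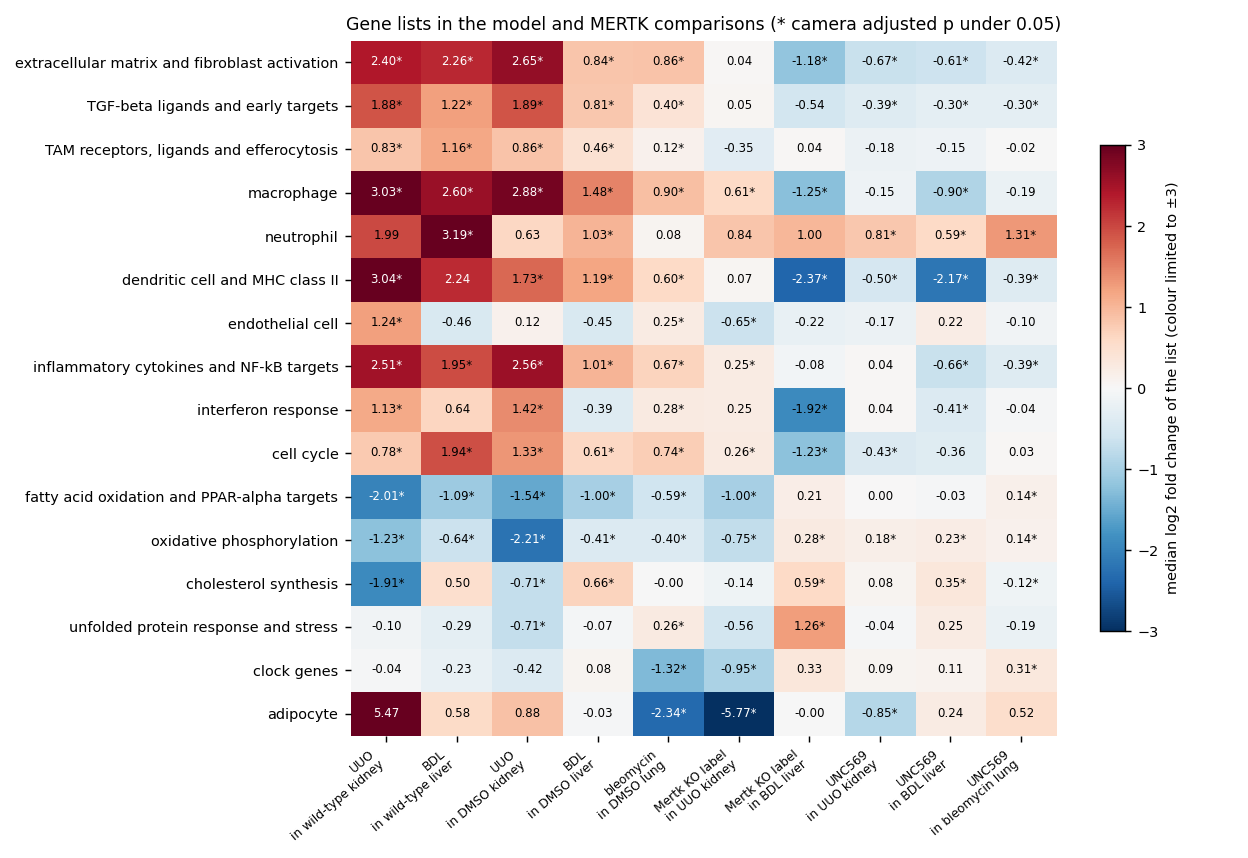
Median log2 fold change of 16 gene lists (vertical) in 10 comparisons (horizontal), with an asterisk where the camera adjusted p was under 0.05. Matrix and macrophage lists are up in each injury, and down with the knockout label and with UNC569 in ligated liver.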

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

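The test for outlying libraries and the exchanges of labels were fixed beforehand, while each test of an explanation was chosen after the result was seen, except that of an effect of UNC569 on kidney. In 106 groups of values, 11 values lay far from the others of their group by Dixon's ratio of gap to range; chance gives about 1 in 20.

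Knockout kidney: the proximal tubule list of sham WT 1 stood at 3.36 (log2) against a nearest value of 10.02 (Dixon 0.904), and UUO WT 1 lacks tubule genes too. A small admixture of another tissue is argued against by the lists themselves, since the higher of both median ratios was 0.0357. That sham WT 1 is liver is in line with its rank correlation, higher by 0.241 with sham liver than with the other sham kidneys.

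Ligated liver by genotype label: whether BDL KO 1 and BDL KO 3 (bad fastq files noted) alone carry the difference cannot be told. Genes chosen from those libraries moved the same way in BDL KO 2 and BDL KO 4 by a mean of 0.227 log2, over 6 choices from -0.02 to 0.53, against a bound of 0.2. A lower share of all non-hepatocyte cells is argued against by list medians only. Endothelial exceeded macrophage by 1.03 (95% interval over genes 0.60 to 1.94), but BDL KO 2 lay within wild type in both. Label and UNC569 effects had r = 0.704 across 530 of the 592 called genes (0.619 to 0.746 with single libraries left out). Reduced MERTK activity or a milder injury could give this, which leaves both open. Over all genes r fell from 0.492 to 0.248 without BDL KO 1 and 3.

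Sham kidney with UNC569: the UUO response differed by UNC569 in 3000 genes, a difference between groups by its own test, and much of it lay in sham. Scaling stays open: 2857 genes passed under median-of-ratios scaling, but the split by direction turned. A different time of day of the sham groups is in line with the clock genes, of which 71.4% passed against 19.3% of all genes (Fisher's exact test p = 3.30e-05). An effect of UNC569 shared by sham and obstructed kidney is argued against, for these genes as a set, by r = -0.388 between them. An effect limited to sham stays open, as does a shared effect on matrix genes, whose list fell in both (median log2 -0.56 and -0.67), and on MHC class II genes (-0.73 and -0.50). If estimated, these list calls end (camera adjusted p = 0.282 to 0.737). Arntl and Npas2 were lower, and 4 of 8 genes of the opposite phase higher.

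Other outlying values follow, with the nearest value. In kidney of the knockout experiment, sham WT 3 was high in matrix genes (6.84 against 4.34 log2, Dixon 0.843), low in reads (7.22 against 14.9 M, Dixon 0.949) and high in unmapped reads (58.5% against 6.59%, Dixon 0.980). Sham KO 4 was low in Mertk (61.0 against 80.5 CPM, Dixon 0.858), and UUO KO 4 high in unmapped reads (32.02% against 8.51%, Dixon 0.837). In liver, sham WT 4 was high in adipocyte genes (3.45 against 2.84 log2, Dixon 0.913), BDL WT 3 low in hepatocyte genes (9.33 against 10.4 log2, Dixon 0.936) and BDL KO 1 high in reads (23.4 against 16.8 M, Dixon 0.858). In the inhibitor experiment, UUO UNC569 1 was high in Mertk (18.3 against 12.9 FPKM, Dixon 0.606) and BDL UNC569 2 in macrophage genes (3.97 against 3.07 log2, Dixon 0.857).

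Exchanged labels gave at least the real count of genes in these numbers of splits, the real labels included. For UUO, 1 of 35 splits reached 6085 in wild-type kidney (highest other 885) and 1 of 35 reached 8517 in DMSO kidney (highest other 5486). For BDL, 1 of 35 reached 3927 in wild-type liver (highest other 0) and 1 of 84 reached 1738 in DMSO liver (highest other 1489). For UNC569, 2 of 100 reached 199 in obstructed kidney (highest other 357) and 1 of 100 reached 3000 for the difference in UUO response (highest other 1564). In ligated liver, 2 of 35 splits reached the 592 genes by genotype label (highest other 1110) and 3 of 100 the 41 genes by UNC569 (highest other 365), and for bleomycin 3 of 84 reached 11 (highest other 1164). Such splits, in obstructed kidney too, point to a structure of the samples other than the labels. Where the real count was 0, every split reached it. These were 35 of 35 by genotype label in obstructed kidney (highest other 0), sham kidney (6) and sham liver (0), and 60 of 60 for the differences in response in kidney (0) and liver (9). They were also 100 of 100 for the difference by UNC569 in BDL response (12), for UNC569 in injured lung (90) and for the difference in lung (938). With 10 splits, too few for a share under 0.05, the real counts were 2961 in sham kidney (highest other 7), 0 in sham liver (14) and 0 in sham lung (713) with UNC569; splits of sham lung also point to a structure of the samples.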

How the results depend on the processing

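Of the alternative values of counts, sets and correlations, 665 stayed the same, 96 moved, 21 lost and 13 gained a call and 4 reversed; of those of gene lists 1883 stayed, 98 lost and 51 gained a call and 3 reversed; of those of named genes 8269 stayed, 955 lost and 41 gained a call and 1 moved. The alternatives behind the doubted libraries, the averaged pair and the cardiac covariate were chosen after the data were seen. The cause of a change was not tested unless stated. The counts by UUO kept within 1.5 times under every alternative, from 4821 to 6558 in wild-type and 7494 to 8682 in DMSO kidney with single libraries left out. FPKM give no depth, so calls near 0 cannot be told from counting noise.

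Under DESeq2 the count of genes by genotype label was 15 in obstructed kidney, 450 in sham kidney and 1908 in ligated liver, and 1944 and 146 for the differences in response in kidney and liver. Without libraries noted to have a bad fastq file it was 717 in sham kidney, 1560 for the kidney difference and 0 in ligated liver. Without sham WT 1 and UUO WT 1 it was 1 in sham kidney. Without BDL KO 1 and BDL KO 3 it was 4 in ligated liver by label and 5951 for BDL in wild type. With no filter, which adds genes to the adjustment, it was 322 in ligated liver by label, 1 by UNC569, 2 in sham liver, 1 for the liver difference and 1 in sham lung. A pseudocount of 0.1 gave 46 by UNC569 in obstructed kidney, 15 in ligated liver and 25 by bleomycin. For bleomycin, median-of-ratios scaling gave 19, the averaged pair 1 and the cardiac covariate 0. The averaged pair gave 1 by UNC569 in sham lung and 1 for the lung difference.

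With single libraries left out, counts by label ranged from 0 to 2649 in sham kidney, 0 to 3480 for the kidney difference, 0 to 1921 in ligated liver and 0 to 44 for the liver difference. For UNC569 they ranged from 7 to 329 in obstructed kidney, 1597 to 3284 in sham kidney and 1963 to 3315 for their difference, and 0 to 143 in ligated liver. BDL in DMSO liver ranged from 730 to 2257. In lung the ranges were 0 to 1911 for bleomycin, 0 to 1 for UNC569 after bleomycin, 0 to 272 in sham and 0 to 691 for the difference.

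Of 632 list tests, 250 passed at the preset correlation and 2 with the estimated correlation. Without the bad fastq libraries the matrix list by label in obstructed kidney reversed to -0.29 (camera adjusted p = 0.0492). Only UUO WT 1 and UUO WT 2 then remained as wild type. With the cardiac covariate the adipocyte list by bleomycin reversed to 0.23. The cardiac list, to which the covariate is fitted, ended at -0.0159, and by UNC569 in injured lung at -0.0115 (camera adjusted p = 0.892).

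For the injury sets, every call at the preset correlation ended with the estimated correlation: kidney rise set -0.22 with UNC569 (adjusted p = 0.577) and 0.20 by label (adjusted p = 0.546), liver rise set -0.71 (adjusted p = 0.300) and -0.56 (adjusted p = 0.546), liver fall set -0.33 by label (adjusted p = 0.712), lung sets -0.31 (adjusted p = 0.512) and 0.20 (adjusted p = 0.577). With 100 genes per set, the kidney sets with UNC569 were -0.16 (adjusted p = 0.135) and 0.18 (adjusted p = 0.0132). The kidney fall set by label reversed to -0.0888 (adjusted p = 0.00239) without sham WT 1, sham WT 3 and UUO WT 1, -0.07 (adjusted p = 0.00476) without UUO WT 1 and -0.82 (adjusted p = 0.0136) without UUO KO 1, the lowest of a range to 0.67 with single libraries left out. The liver fall set by label was -0.0315 (adjusted p = 0.504) without BDL KO 1 and BDL KO 3, and -0.778 to -0.0312 with single libraries left out. Other such ranges were -0.27 to -0.12 and -0.11 to 0.12 for the kidney rise and fall sets with UNC569, 0.0842 to 0.380 for the kidney rise set by label and -0.0648 to 0.00849 for the liver fall set with UNC569. Both effects in liver had r = 0.248 without BDL KO 1 and 3.

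A replicate block gave 239 genes in ligated liver by label and kept every other count by label or injury within 1.5 times. It ended 20 calls of named genes, among them Mertk by BDL (adjusted p = 0.0521) and, by label in ligated liver, Col6a3, Trib3, Ecm1, Tle1, Irf2bp2, Hspa1b, Atg2a, Rcl1 and Ifit1 (adjusted p = 0.0532 to 0.0664). Of lists, it ended bile acid genes by BDL (adjusted p = 0.0555) and added adipocyte genes by UUO (0.0427) and tubular injury genes by label in obstructed kidney (0.0401). Deviations of same-numbered libraries correlated from -0.338 to 0.298 over 24 pairs, 8 of them over 0.1, and 7 libraries correlated best with their own number, so numbers were not taken as pairs. In the inhibitor experiment the columns carry no replicate numbers, so no paired analysis was possible, and the 2 UUO libraries with differing titles were not left out.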

Other observations

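Further gene groups moved in sham kidney with UNC569 (3 against 3 libraries). Of 12 endothelial genes, 0 rose and 10 fell (0 and 12 adjusted over the list alone, median log2 -1.06, camera adjusted p = 3.73e-09, adjusted p = 0.282 if estimated). Of 16 stress genes, 0 rose and 9 fell (0 and 10 adjusted over the list alone, median log2 -0.91, camera adjusted p = 1.82e-08, adjusted p = 0.132 if estimated). Of 14 complement and acute phase genes, 0 rose and 9 fell (0 and 12 adjusted over the list alone, median log2 -1.25, camera adjusted p = 7.02e-07, adjusted p = 0.282 if estimated).

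The SD of the log2 difference between lung libraries sham DMSO 0 and 1 was 0.406, the lowest of any pair in a lung group.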
